A study of Oryza sativa with 4 samples.

How the data were processed

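Total RNA of tricellular pollen (TCP, 2 biological replicates) and pollen mother cells (PMC, 2 biological replicates) of rice cultivar Nipponbare was isolated with a PicoPure kit and labelled with Cy3, per the labels. RNA of 1-week-old seedlings was labelled with Cy5 and hybridised on each of the 4 arrays, per the labels, so dye orientation was the same on all arrays and no dye swap exists. The arrays were the 4 fields of 1 rice oligonucleotide slide read in 1 scan, so slide and scan could not be used as a block. Each field held 45151 spots.

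Mean spot brightness and median local background per channel are unprocessed intensity values from Feature Extraction 9.5.3.1, per the file headers. Processed signals are intensity values that the software background-subtracted, detrended and dye-normalised, with dim spots replaced by surrogates, per the file headers. The deposited log ratio is the log10 of the processed Cy5 signal over the processed Cy3 signal, per the file headers. The deposited value table holds log2 ratios of Cy3 over Cy5. It was checked against the scanner files and equals the log ratio with its sign turned and its base changed (r = 1 on every array, largest difference 0.0053), with a median of 0 on each array. Spot flags were used as the software gave them, and a spot is well above background where its signal exceeds the background by 13 standard deviations, per the file headers. The headers state no genome build, so no coordinates are given.

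From the mean and background intensities, background was corrected by normexp with an offset of 50 over all spots, and each array was normalised within itself by loess with control spots at weight 0. Ratios were turned to log2 of the male sample over seedling. Control spots were then left out, spots with a non-uniformity or population outlier flag in either channel were set to missing, and spots of 1 probe were averaged. Saturated spots were kept. Work was done in R 4.3.3 with limma 3.58.1 and the package data.table (version 1.17.8), and figures were drawn with matplotlib 3.10.9.

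The design, the gene lists, the rule for naming genes and most alternative settings were fixed before the data were examined. limma's lmFit and eBayes were fitted over the 4 arrays with TCP and PMC as groups (2 residual degrees of freedom, prior degrees of freedom 2.67). TCP and PMC ratios were each tested against 0, which is the comparison with seedling, and against each other. Tests were two-sided. A comparison was adjusted by the Benjamini-Hochberg method over the probes well above background on both arrays of at least 1 of its sides, and a probe was called at an adjusted p under 0.05. For genes with several probes the probe with the highest mean intensity was used, and disagreement in sign between probes is stated for named genes.

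There were 3 lists fixed by locus (meiosis, tapetum and anther wall, pollen) and 29 fixed by words in the probe descriptions. Lists with at least 5 tested genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison. They were tested again with an estimated correlation, which takes p from the 2 residual degrees of freedom, so hardly any list could pass. Bounds for probes dim on 1 side came from single-channel log2 signals after loess and Aquantile, and were left out of the text where the fitted ratio or the Cy3 channel alone gave less. List medians use fitted ratios, including those of genes dim on 1 side, which depend on the offset. Rop GTPase signalling had 4 members with a probe and was not tested. Locus list symbols were set from general knowledge. Of 64 such loci, 33 had the same symbol on the same chromosome in the RefSeq table of assembly ASM3414082v1, which was used for names alone. Before values were read, 2 loci were left out because their descriptions contradicted the symbol, and 3 members had no probe.

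Named genes were chosen by rule for each comparison. The rule took, among genes past the threshold, the highest and lowest log2 ratios measured on both sides with an informative description, the largest bounds in each direction, up to 2 highest and 2 lowest called members of each list described, and any member of the locus lists. The text names 70 of the genes the rule gives.

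Alternatives were the software's processed signals, no background correction, median centring, loess followed by Aquantile, no filter on dim probes, only probes well above background in both channels on all arrays, flagged spots kept, at least 2-fold, an adjusted p under 0.01, replicate number as a block, each replicate left out, a prior variance trend, the deposited value table, a single probe per gene, and for TCP against PMC the Cy3 channel alone scaled at its 75th percentile. After the data were seen, lists without members matched by accident were added, and so were probes whose seedling signal differed by under 2-fold between TCP and PMC arrays.

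The fit was tested on simulated data with 50 probes changed at each of 4 fold sizes. For TCP against PMC (31649 probes) it called 0% of 2-fold, 6% of 4-fold, 82% of 16-fold and 94% of 64-fold changes, with 4 unchanged probes called. For TCP against seedling (35355 probes) it called 0%, 44%, 96% and 100%, with 10 unchanged probes called, and for PMC against seedling (35426 probes) 0%, 38%, 92% and 100%, with 9 unchanged probes called. In the data, 60%, 74.7% and 59.4% of tested probes were called in these 3 comparisons. With so few probes changed in the simulation, its Benjamini-Hochberg threshold was stricter than that of the data. The simulated rates therefore do not give the sensitivity or the false calls of the reported comparisons. In a further simulation of TCP against PMC, over 21867 genes, camera at the preset correlation passed 3 of 3 lists shifted lower by 2 on the log2 scale. It passed 0 of 20 random lists. Noise was drawn independently for each probe, so genes of a simulated list were uncorrelated. Cytosolic ribosomal proteins had an estimated correlation of 0.299 in the data, so the simulation says nothing of false calls for lists with correlated genes. Scanner control spots were left out of all comparisons.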

Results

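Transcript levels were measured in tricellular pollen (TCP) and in pollen mother cells (PMC) of rice, cultivar Nipponbare, each against RNA of 1-week-old seedlings of the same cultivar. Tricellular pollen is the mature male gametophyte, made of a vegetative cell and a pair of sperm cells. Pollen mother cells are the diploid anther cells that enter meiosis. The data were 4 dual-colour oligonucleotide arrays with the male sample in the Cy3 channel and seedling RNA in the Cy5 channel of every array. TCP and PMC had 2 biological replicates each, and the 4 arrays carried 4 seedling replicates whose biological or technical nature the labels do not state. All 4 arrays lay on 1 slide and were read in 1 scan. After spots of 1 probe were averaged, 42429 probes remained, and 41908 of them named 29690 loci.

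Fewer probes were detected in pollen than in the other RNAs. Of the 42429 probes, 59.7% ± 0.516 (SD, n = 2) lay well above background in TCP, 73.5% ± 2.99 (SD, n = 2) in PMC and 81.5% ± 2.20 (SD, n = 4) in seedling. Per array, 25169 and 25478 probes were detected in TCP, 30279 and 32073 in PMC, and between 33991 and 35967 in seedling. The signal of TCP was also carried by fewer transcripts, with 38.0% ± 3.25 (SD, n = 2) of it on the brightest 1% of spots, against 15.7% ± 1.56 (SD, n = 2) in PMC and 17.6% ± 0.340 (SD, n = 4) in seedling. An exact permutation of 2 arrays against 2 cannot give a two-sided p under 0.333, so these shares were not tested. On both arrays of a group, 23071 probes were detected in TCP and 29086 in PMC, and 20508 in both. A further 1379 probes were detected on both TCP arrays and on neither PMC array, and 5616 the other way round. The Cy3 channel was dimmer on the TCP arrays, with a median spot signal of 402.1 and 348.5, against 2324 and 2727 on the PMC arrays. How much of the lower detection in TCP follows from less labelled signal was not tested. Detection on both arrays of TCP with none in PMC or seedling held for 461 probes, and on both arrays of PMC with none in TCP or seedling for 352. The number of arrays limits the precision of every value. Comparisons of these values with seedling are confounded with dye, since TCP and PMC were in Cy3 and seedling in Cy5. Of random control spots, 10% were well above background in Cy3 and 3.33% in Cy5, and the probe counts were not corrected for such signal.

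**Figure D1:**
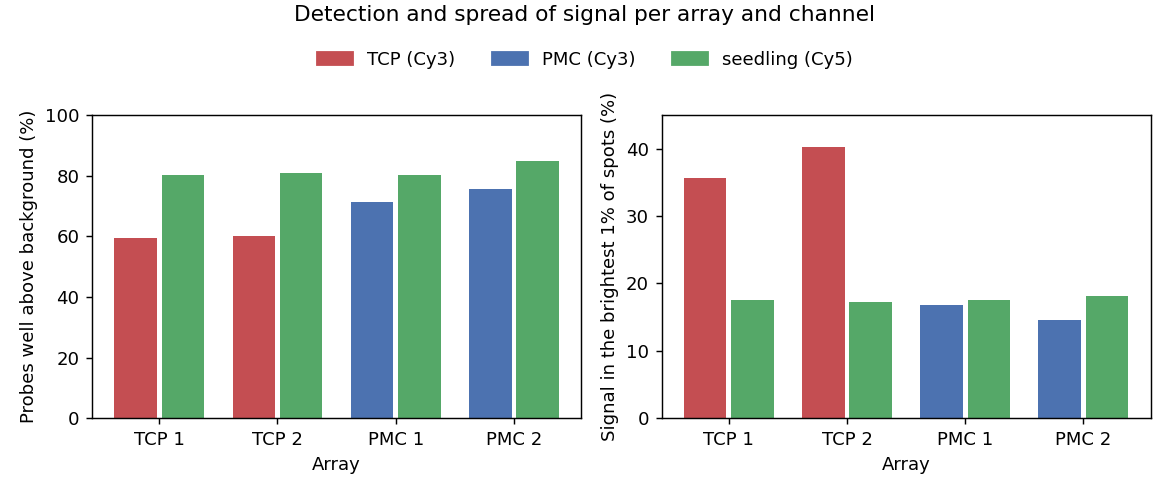
The left panel gives the percent of 42429 probes well above background and the right panel the percent of summed signal on the brightest 1% of spots, with 1 bar per array and channel. The TCP bars are the lowest of the left panel (59.3% and 60.0%) and the highest of the right panel (35.7% and 40.3%).

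Replicates of a group lay close together. Across 36528 probes, which are not independent replicates, the log2 ratios to seedling had Pearson's r = 0.959 between the TCP arrays and 0.927 between the PMC arrays, and 0.490 to 0.538 between a TCP and a PMC array. Seedling signals had r = 0.997 between the TCP arrays, 0.998 between the PMC arrays and 0.974 to 0.975 across them.

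The comparison of pollen mother cells with seedlings asks which transcripts set cells about to undergo meiosis apart from vegetative tissue. Meiosis needs programmed DNA breaks, homologous pairing and a synaptonemal complex, whose proteins have little known use elsewhere. Pollen mother cells lie inside the anther wall, next to the tapetum, the nurse layer that feeds them and makes pollen wall material. Of 35426 probes tested, 21050 changed, 9296 higher and 11754 lower in PMC (limma, Benjamini-Hochberg adjusted). The balance turned for probes with both channels well above background on all arrays, with 6371 higher and 4963 lower (56.2% higher). By gene, 14570 of 24446 changed, 6876 higher and 7694 lower. Seedling RNA was in Cy5 on every array, so a dye effect of a probe remains in each of these ratios.

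Meiosis genes were higher in PMC. Of 25 meiosis genes fixed as a list and tested, 24 were higher than in seedling and 0 lower, with the same counts when adjusted over the list alone. The list had a median log2 ratio of 3.73, limma's camera adjusted p = 6.77e-09, and adjusted p = 0.355 with an estimated correlation. The Argonaute gene MEL1 (Os03g0800200) had a log2 ratio of 5.97 ± 0.13 (SD, n = 2, limma adjusted p = 0.000144). The pairing gene PAIR1 (Os03g0106300) had 5.56 ± 0.30 (SD, n = 2, limma adjusted p = 0.000286) and the strand exchange gene DMC1B (Os11g0146800) 5.48 ± 0.26 (SD, n = 2, limma adjusted p = 2e-04). SPO11-1 (Os03g0752200), for the enzyme that cuts DNA at the start of recombination, was 13.2-fold higher. The cohesion protector SGO1 (Os02g0799100) was the member not called, at 0.42 ± 0.60 (SD, n = 2, limma adjusted p = 0.279). On both PMC arrays 25 of the 26 meiosis genes with a probe (96.2%) were well above background, against 67.0% of all genes.

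Tapetum and anther wall genes were higher in PMC as well. Of 20 tested, 18 were higher and 1 lower, also when adjusted over the list alone, with a median log2 ratio of 5.92 (camera adjusted p = 8.56e-08, and adjusted p = 0.355 with an estimated correlation). Both PMC arrays had 20 of the 25 genes with a probe (80%) well above background. The transcription factor gene TIP2 (Os01g0293100) reached 8.03 ± 0.03 (SD, n = 2, limma adjusted p = 0.000123) and UDT1 (Os07g0549600) was 85.5-fold higher. For a probe not well above background in 1 of the RNAs, only a bound can be given. The bound is the brighter mean over the dim probe's own signal or the lowest signal that counts as well above background, whichever is higher, on channel signals after loess and Aquantile. It holds on that scale and remains open to dye bias. Where the fitted ratio or the Cy3 channel alone gave less, the value of this rule is no lower limit and is left out. On that basis the polyketide synthase gene PKS1 (Os10g0484800) was at least 227-fold higher in PMC. The aspartic protease gene AP25 (Os03g0186900) was the lower member at -4.77. The gene C4 (Os08g0546300) differed between the PMC arrays (2.53 ± 4.14, SD, n = 2, limma adjusted p = 0.172) and passed when PMC replicate 1 was left out (5.47, limma adjusted p = 0.00435). Genes known from the cell layers around PMC were thus among those measured in the PMC samples.

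Among single genes measured on both sides, a MADS-box gene (Os08g0531700) stood at the top with a log2 ratio of 8.36 ± 0.21 (SD, n = 2, limma adjusted p = 0.000155). An aspartic peptidase family gene (Os08g0207800) reached 8.24 and a further MADS-box gene (Os09g0507200) 7.70. An F-box gene (Os07g0189400) was at least 206-fold and an ARM repeat gene (Os12g0493900) at least 224-fold higher. The MADS-box list had 20 of 33 genes higher and 5 lower (median 1.71, camera adjusted p = 0.00199), and F-box genes 195 of 320 higher and 29 lower (1.42, adjusted p = 3.18e-10). RNA silencing genes, which include MEL1 and the Piwi domain gene Os04g0615800 (18.1-fold higher), had 7 of 13 higher and 1 lower (2.14, adjusted p = 0.0228). Over the 11 of them whose seedling signal differed by under 2-fold between TCP and PMC arrays, a choice that dropped higher members, the median was 0.90 and camera did not pass (adjusted p = 0.0935). Recombination and cohesion genes had 17 of 31 higher and 2 lower (1.21, adjusted p = 0.00200), and heat shock proteins 54 of 121 higher and 27 lower (0.78, adjusted p = 0.0179). Each of these 5 lists had adjusted p = 0.355 with an estimated correlation.

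Photosynthesis, peroxidase and lignin, lipid transfer and expansin lists were among those lower in PMC. Photosynthesis genes had 64 of 82 lower and 10 higher (median -5.11, camera adjusted p = 3.18e-10), or 46 of 54 lower and 5 higher without members whose descriptions matched by accident (median -6.87, adjusted p = 2.27e-11). A Rubisco small subunit (Os12g0292400) stood at -9.08. Peroxidases and lignin enzymes had 123 of 143 lower and 9 higher (-3.78, adjusted p = 2.12e-16), with an anionic peroxidase (Os04g0688100) at -7.22. Lipid transfer proteins had 22 of 30 lower and 3 higher (-4.79, adjusted p = 5.01e-06), including LTP 1 (Os12g0115100) at -9.90. Expansins and pollen allergens had 29 of 40 lower and 1 higher (-2.09, adjusted p = 2.6e-05), with the alpha-expansin EXPA2 (Os01g0823100) at -7.68. WRKY factors had 38 of 66 lower (-1.80, adjusted p = 0.00136), auxin genes 46 of 88 (-1.28, adjusted p = 0.0246), and sugar transport and invertase genes 33 of 63 (-1.10, adjusted p = 0.0276). These 7 lists had adjusted p = 0.355 with an estimated correlation, except auxin with 0.410. The root protein gene RCc3 (Os02g0662000) was 1550-fold lower, an isocitrate lyase family gene (Os12g0189300) 1120-fold lower, and a nicotianamine synthase (Os03g0307300) at least 1900-fold lower.

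In all, 14 of 30 lists passed in PMC against seedling, 7 higher and 7 lower, and 0 passed camera with an estimated correlation, where 3 had an unadjusted p under 0.05. Adjusted over the list alone, the counts were 67 lower for photosynthesis and 126 lower for peroxidases and lignin. Cytosolic ribosomal proteins had 41 higher and 20 lower of 236 (median 0.16, camera adjusted p = 0.160), and they passed under median centring (adjusted p = 0.0134) and without PMC replicate 2 (adjusted p = 0.0276). Median centring also gave calls to proteasome (median 0.61, adjusted p = 0.00609), vesicle trafficking (0.55, 0.0134), DNA replication (0.96, 0.0478) and pectin enzyme lists (-0.91, 0.0452), none of which passed as reported. Tubulins had a median of 0.19 and a mean of -0.40, cyclins a median of -0.06 with a camera direction upwards, and pentatricopeptide repeat genes a median of -0.28 and a mean of 0.68. None of these 3 passed (camera adjusted p = 0.919, 0.992 and 0.772).

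The comparison of tricellular pollen with seedlings asks what the mature male gametophyte expresses that vegetative tissue does not. Mature pollen germinates on the stigma and grows a tube through the style, which needs wall material and transport. Of 35355 probes tested, 26410 changed, 12548 higher and 13862 lower in TCP (47.5% higher), and median centring gave 10013 higher and 16966 lower (37.1% higher). The balance turned for probes with both channels well above background on all arrays, with 10017 higher and 5884 lower (63.0% higher), and was 51.2% and 51.7% higher without TCP replicate 1 or 2. The filter on both channels leaves out probes detected on 1 side only. More probes were detected in seedling than in TCP, so the turn towards higher follows in part from the filter. By gene, 18211 of 24521 changed, 9540 higher and 8671 lower. The median over all genes was 0.05 as reported, -0.64 under median centring and -0.51 with the scanner software's own normalised signals. List medians are given relative to all genes where these settings are compared.

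The largest ratios measured on both sides were those of a B12D family gene (Os07g0274400, 11.39 ± 0.59, SD, n = 2, limma adjusted p = 9.45e-05), a C2 domain gene (Os07g0108500, 11.24) and a pectin methylesterase inhibitor domain gene (Os01g0253200, 11.23). A reticulon family gene (Os05g0312500) was at least 3510-fold and an oligopeptide transporter (Os05g0252000) at least 3440-fold higher. Of the pollen genes fixed as a list, 5 of 7 were higher and 1 lower than in seedling, also when adjusted over the list alone (median 5.45, camera adjusted p = 0.0565, adjusted p = 0.503 with an estimated correlation). The list passed under median centring (camera adjusted p = 0.00690), with the scanner software's signals (camera adjusted p = 0.0245) and without TCP replicate 2 (0.0461, median 4.94). Over the 5 genes with similar seedling signal on TCP and PMC arrays it had 0.217 at a median of 5.45. The MADS-box genes MADS63 (Os06g0223300) and MADS68 (Os11g0658700) were at least 2270-fold and at least 2140-fold higher. The sperm fusion gene GCS1 (Os05g0269500) had 5.45 ± 0.26 (SD, n = 2, limma adjusted p = 0.000446). The gene at Os06g0152100, described as Profilin 2, was the lower member at -6.05. Pectin enzymes had 44 of 78 higher and 23 lower (median 2.19, camera adjusted p = 0.0141), among them a pectate lyase homologue (Os06g0583900) at 10.31. Restricted to probes whose seedling signal differed by under 2-fold between TCP and PMC arrays, the median of pectin enzymes relative to all genes was -0.63 (camera adjusted p = 0.321). This choice drops some bright pollen genes.

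Several meiosis genes were also higher in pollen than in seedling. Of 21 tested, 15 were higher and 0 lower, also when adjusted over the list alone (median 1.39, camera adjusted p = 0.0109), and median centring gave 8 higher and 5 lower (camera adjusted p = 0.148), with the median relative to all genes at 0.80 against 1.34 as reported. MSH4 (Os07g0486000) was at least 132-fold higher, DMC1A (Os12g0143800) 83.5-fold and MEL2 (Os12g0572800) 83.3-fold. The folds of single genes here are on the loess scale. Under median centring the log2 differences of TCP minus PMC were negative for MSH4, DMC1A and MEL2 (-0.37, -1.65 and -1.29). Tapetum and anther wall genes had 5 higher and 3 lower of 14 (median 0.52, camera adjusted p = 0.638). TDL1A (Os12g0472500), the ligand gene that limits how many cells enter meiosis, was 248-fold higher, and the cytochrome P450 gene CYP703A3 (Os08g0131100) at least 62.4-fold higher. F-box genes had 200 of 299 higher and 44 lower (median 2.50, adjusted p = 2.72e-06), with Os10g0133100 at 7.62. Recombination and cohesion genes (19 of 31 higher, 5 lower, adjusted p = 0.0377), MADS-box genes (16 of 29 higher, 3 lower, adjusted p = 0.0152) and transposable elements (42 of 73 higher, 12 lower, adjusted p = 0.0123) passed as well, and none of these 3 passed under median centring (adjusted p = 0.182, 0.0690 and 0.0690), where their medians relative to all genes went from 2.17, 1.56 and 1.62 to 1.12, 1.32 and 1.26. Recombination and cohesion genes also missed the threshold with the scanner software's signals (0.0753) and without TCP replicate 1 (0.0773), at relative medians of 2.09 and 1.66. Pectin enzymes and the 5 lists passing here had adjusted p = 0.503 with an estimated correlation.

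Photosynthesis, ribosomal protein and histone genes were among those lower in pollen. Photosynthesis genes had 67 of 81 lower and 9 higher (median -3.60, camera adjusted p = 2.78e-10). Without members whose descriptions matched by accident the counts were 49 of 52 lower and 1 higher (median -6.83, adjusted p = 1.11e-13). Members included a chlorophyll a-b binding protein (Os01g0600900) at -8.80 and a Rubisco small subunit (Os12g0274700) at -8.81. Cytosolic ribosomal proteins had 188 of 236 lower and 26 higher (-3.24, adjusted p = 3.99e-14). The S3a gene (Os03g0200500) stood at -7.07 ± 0.34 (SD, n = 2, limma adjusted p = 0.000107), while an L24/L26 family gene (Os02g0772000) was 325-fold higher. Histones had 37 of 50 lower and 6 higher (-2.11, adjusted p = 8.72e-06), with a histone H2A (Os03g0279200) at -7.78. Lipid transfer proteins had 20 of 29 lower (-4.51, adjusted p = 2.5e-05), peroxidases and lignin enzymes 97 of 142 (-1.65, adjusted p = 1.83e-06) and auxin genes 47 of 85 (-1.35, adjusted p = 0.00836). Proteasome genes had 37 of 54 lower (-1.42, adjusted p = 0.000148) and tubulins 12 of 20 (-1.68, adjusted p = 0.0138), and neither passed under median centring (adjusted p = 0.149 and 0.262) or with the scanner software's signals (adjusted p = 0.0600 and 0.121). Relative to all genes, the proteasome median was -1.47 as reported, -0.16 under median centring and -0.39 with the scanner software's signals, and that of tubulins -1.73, -0.62 and -0.95. Lower proteasome genes numbered 26 under either setting and 23 without TCP replicate 2. These 8 lists had adjusted p = 0.503 with an estimated correlation. A sucrose synthase (Os06g0194900) was 334-fold lower and a phenylalanine ammonia-lyase (Os02g0626100) at least 752-fold lower.

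In TCP against seedling 14 of 31 lists passed, 6 higher and 8 lower, and 0 passed camera with an estimated correlation, where 1 had an unadjusted p under 0.05. Adjusted over the list alone, peroxidases and lignin had 100 lower and recombination and cohesion 23 higher. Expansins and pollen allergens had a median of -0.32 and a mean of 1.25, actin genes -0.64 and 0.26, and calcium signalling genes -0.87 and 0.29, with camera's direction downwards in each (adjusted p = 0.850, 0.533 and 0.225). Restricted to probes whose seedling signal differed by under 2-fold between TCP and PMC arrays, expansins and pollen allergens passed as lower (7 higher and 28 lower of 40, median -1.94, adjusted p = 0.00377), as did calcium signalling genes (25 and 56 of 103, -1.23, adjusted p = 0.0175). The restriction took higher members from 24 to 7 and from 38 to 25 and left 28 and 56 lower ones. Both calls thus follow from the loss of higher members. WRKY factors (median -0.73, adjusted p = 0.209) passed as lower under median centring (-1.53, 0.0452) and with the scanner software's signals (-2.66, 0.0388). The mitochondrial respiratory chain list (median 0.41, adjusted p = 0.336) passed as higher under both (1.70, 0.000142 and 1.18, 0.00857).

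The comparisons with seedling were set side by side to count the calls of the early and the late male stage that go the same way. Of 33944 probes tested in both, 5077 were higher in both stages, where independent calls would share 2705, and 8112 were lower in both, where they would share 4754. Opposite calls numbered 1346 probes higher in TCP and lower in PMC against 3840, and 1438 lower in TCP and higher in PMC against 3349. Seedling RNA in the same dye enters both comparisons, so independence is a reference figure and not what would be seen with no shared change. What the common reference and dye alone would give was not estimated, and the excess was not tested.

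The comparison of tricellular pollen with pollen mother cells follows the male line from before meiosis to the mature grain. It takes the difference of the ratios to seedling, so a dye effect common to all arrays cancels. Of 31649 probes tested, 18997 changed, 10869 higher and 8128 lower in TCP (57.2% higher). This split depended on the scaling, with 7154 higher and 12012 lower (37.3% higher) under median centring and 7663 higher and 9866 lower (43.7% higher) with the scanner software's signals. By gene, 13378 of 21867 changed, 8139 higher and 5239 lower. The median over all genes was 0.49 as reported, -0.54 under median centring, -0.19 with the scanner software's signals and 0.26 from the Cy3 channel alone.

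Pollen genes were higher in TCP. Of 7 tested, 6 were higher and 1 lower, also when adjusted over the list alone, with a median of 5.85, or 5.36 relative to all genes (camera adjusted p = 0.0329, and adjusted p = 0.679 with an estimated correlation). The relative median lay between 5.36 and 9.84 over the 4 scalings, and camera no longer passed without TCP replicate 2 (adjusted p = 0.0546, relative median 5.23) or without PMC replicate 1 (adjusted p = 0.114, relative median 5.57). It did not pass either over the 5 genes whose seedling signal differed by under 2-fold between TCP and PMC arrays (adjusted p = 0.157), where the median was 7.37, or 6.98 relative to all genes. MADS63 (Os06g0223300) was at least 1740-fold higher than in PMC, with a log2 difference of 10.98 in the Cy3 channel alone. MADS68 (Os11g0658700) was higher and not well above background in PMC, with log2 differences of 10.76 as fitted and 10.10 in the Cy3 channel alone. The sucrose transporter SUT1 (Os03g0170900) was 166-fold higher, with ratios to seedling of 0.59 ± 0.42 (SD, n = 2) in TCP and -6.79 ± 0.10 (SD, n = 2) in PMC (limma adjusted p = 0.000637). GCS1 (Os05g0269500) was 41.5-fold higher, and the gene at Os06g0152100 was lower (-4.36). On both arrays of the group, 7 of the 8 pollen genes with a probe were detected in TCP and 3 in PMC.

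Wall remodelling genes were higher in TCP, and the sugar transport and invertase list passed as higher only with inhibitor genes in it. Pectin enzymes had 42 of 66 higher and 8 lower, also when adjusted over the list alone (median 3.46, relative 2.97, camera adjusted p = 0.000183, adjusted p = 0.592 with an estimated correlation). Their relative median was 3.84 under median centring, 3.21 with the scanner software's signals and 7.02 in the Cy3 channel alone. Expansins and pollen allergens had 29 of 46 higher and 8 lower (2.78, relative 2.29, adjusted p = 0.0144, and 0.679 with an estimated correlation). Sugar transport and invertase genes had 33 of 55 higher and 5 lower (2.23, relative 1.74, adjusted p = 0.00495, and 0.592 with an estimated correlation). Without inhibitor genes whose descriptions matched by accident the list missed the threshold (adjusted p = 0.0867), with 23 of 43 higher, 4 lower and a median of 1.75, or 1.26 relative to all genes. No member was taken out of the pectin list, whose search words also match pectin methylesterase inhibitors. Of genes with a probe, 19 of 91 pectin enzymes and 21 of 82 sugar transport and invertase genes were also in another list. Lists are thus not independent of each other. None of these 3 lists passed when restricted to probes whose seedling signal differed by under 2-fold between TCP and PMC arrays (adjusted p = 0.904, 0.904 and 0.167, medians 0.39, 0.87 and 1.59). The restriction drops some bright pollen genes. A beta-expansin (Os10g0548600) and a pectinesterase (Os11g0683800) were higher and not well above background in PMC. The seedling channel of the same probes was also brighter on the TCP arrays, by 4.15 and 3.99 on the log2 scale. Their fitted log2 differences were 9.25 and 9.13, and those from the Cy3 channel alone were 15.24 and 15.29. Among genes measured in both TCP and PMC, a GRAM domain gene (Os06g0607900) led at 10.09 (standard error 0.49, limma adjusted p = 0.000591), with a seedling signal not well above background. A TPR-like gene (Os01g0951800) followed at 9.31 and an amino acid transporter family gene (Os12g0574000) at 9.03. In the Cy3 channel alone the order was another, with 8.92 for the GRAM domain gene, 10.59 for the TPR-like gene and 8.41 for the transporter. A pectate lyase (Os06g0144900) was 165-fold higher, while the beta-expansin EXPB4 (Os10g0556100) was 88.4-fold lower.

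Meiosis genes were lower in TCP. Of 25 tested, 12 were lower and 4 higher, also when adjusted over the list alone, with a median of -1.50, or -1.99 relative to all genes (camera adjusted p = 0.00415, and adjusted p = 0.679 with an estimated correlation). The synaptonemal complex gene ZEP1 (Os04g0452500) and COM1 (Os06g0613400) were lower and not well above background in TCP, with log2 differences of -4.99 and -4.93 as fitted and -3.79 and -3.28 in the Cy3 channel alone. DMC1B (Os11g0146800) differed by -3.54 (limma adjusted p = 0.00225) and PAIR2 (Os09g0506800) by -3.46 (limma adjusted p = 0.00178). The 4 higher members were MSH4 (Os07g0486000, 1.97), MEL2 (Os12g0572800, 1.57), RAD51C (Os01g0578000, 1.29) and DMC1A (Os12g0143800, 1.25, limma adjusted p = 0.0497), and each of the 4 had a negative difference under median centring and from the Cy3 channel alone. The seedling signal of MEL2 was lower on the TCP arrays (-1.48 on the log2 scale), which raises its fitted difference. DMC1A lost its call when any of the replicates was left out (adjusted p = 0.0620 to 0.201). RAD51C lost it without TCP replicate 1 (0.0844), TCP replicate 2 (0.110) or PMC replicate 1 (0.0566), MEL2 without TCP replicate 1 (0.0808) or 2 (0.0563), and MSH4 without TCP replicate 2 (0.0504). Probes of HEI10, RPA1A and SGO1 disagreed in sign. The counts of the list moved with the setting, with 20 lower and 0 higher under median centring (median -3.55), 15 and 0 in the Cy3 channel alone, 13 and 0 with the scanner software's signals, and 7 to 11 lower with 0 to 3 higher when a replicate was left out. Both TCP arrays had 18 of 26 meiosis genes (69.2%) above background.

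Tapetum and anther wall genes were lower in TCP than in PMC. Of 22 tested, 14 were lower and 3 higher, also when adjusted over the list alone (median -3.74, relative -4.24, camera adjusted p = 4.32e-05, adjusted p = 0.592 with an estimated correlation). TIP2 (Os01g0293100) and TDR (Os02g0120500) were lower and not well above background in TCP, with log2 differences of -7.62 and -7.19 as fitted and -8.61 and -7.07 in the Cy3 channel alone. TDL1A (Os12g0472500) was higher at 2.27 (limma adjusted p = 0.00767), a direction that turned under median centring and in the Cy3 channel alone. The transporter ABCG15 (Os06g0607700) was at least 16.4-fold higher. The third higher member, PTC1 (Os09g0449000, 2.93, limma adjusted p = 0.0303), lost its call without TCP replicate 1 (2.10) or PMC replicate 1 (2.18). CYP703A3 (Os08g0131100) was not called as fitted (-0.04, limma adjusted p = 0.945), though it was lower under median centring (-2.16) and in the Cy3 channel alone (-3.03). The seedling signal of CYP703A3 was lower on the TCP arrays (-1.69 on the log2 scale), which raises the fitted difference. A lipid transfer domain gene (Os03g0663900) was lower and not well above background in TCP, with log2 differences of -6.19 as fitted and -9.92 in the Cy3 channel alone. Its seedling signal was also lower on the TCP arrays (-4.99). Single genes measured on both sides were lowest for a beta-ketoacyl-CoA synthase (Os03g0181500) at -7.70 and a homocysteine S-methyltransferase (Os12g0607000) at -7.40.

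**Figure D2:**
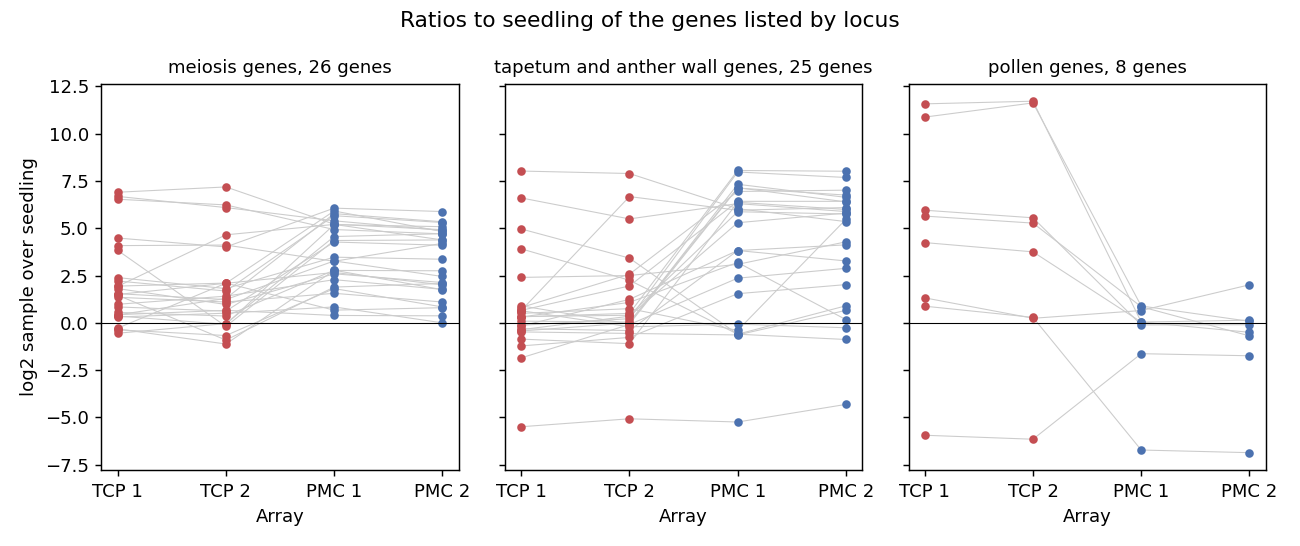
Each line is 1 gene of a list fixed by locus, with its log2 ratio of sample over seedling on the vertical axis and the 4 arrays on the horizontal axis, TCP in red and PMC in blue. In the difference of TCP minus PMC, meiosis genes had a median of -1.50, tapetum and anther wall genes -3.74 and pollen genes 5.85, and these 3 signs held under each of the 4 scalings.

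Genes for protein synthesis and turnover were lower in TCP. Cytosolic ribosomal proteins had 186 of 232 lower and 12 higher, or 191 and 14 when adjusted over the list alone (median -3.52, relative -4.01, camera adjusted p = 3.28e-23, adjusted p = 0.679 with an estimated correlation). The S23 gene (Os01g0834500) was 66.8-fold lower, with -4.97 ± 0.42 in TCP and 1.09 ± 0.14 in PMC (SD, n = 2 each, limma adjusted p = 0.000888). An L12 gene (Os05g0568300) was 12.6-fold higher. Proteasome genes had 39 of 55 lower and 2 higher, or 44 and 2 when adjusted over the list alone (-1.59, relative -2.08, adjusted p = 3.45e-08), with a p42 subunit (Os02g0199900) at -3.79. The proteasome median relative to all genes was smaller under median centring (-0.89, 31 lower), with the scanner software's signals (-0.94, 23 lower) and in the Cy3 channel alone (-0.84, 15 lower), and 25 and 17 genes were lower without TCP replicate 1 or 2. Histones had 32 of 48 lower and 4 higher (-1.93, relative -2.42, adjusted p = 6.31e-07). Their relative median was smaller under median centring (-1.34) and with the scanner software's signals (-1.66). In the Cy3 channel alone it was -1.34, with 22 lower and 7 higher. The histone H2A gene (Os03g0279200) was 29.2-fold lower and a histone H2B.1 gene (Os01g0149400) 39.0-fold higher. Tubulins had 13 of 20 lower and 2 higher (-1.90, relative -2.39, adjusted p = 0.00112), and the list missed the threshold under median centring (adjusted p = 0.138) and in the Cy3 channel alone (adjusted p = 0.151), at relative medians of -1.91 and -1.81. A beta tubulin (Os01g0282800) was 26.9-fold lower while the beta-3 tubulin (Os03g0661300) was 72.8-fold higher. Proteasome, histone and tubulin lists had adjusted p = 0.679 with an estimated correlation.

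**Figure D3:**
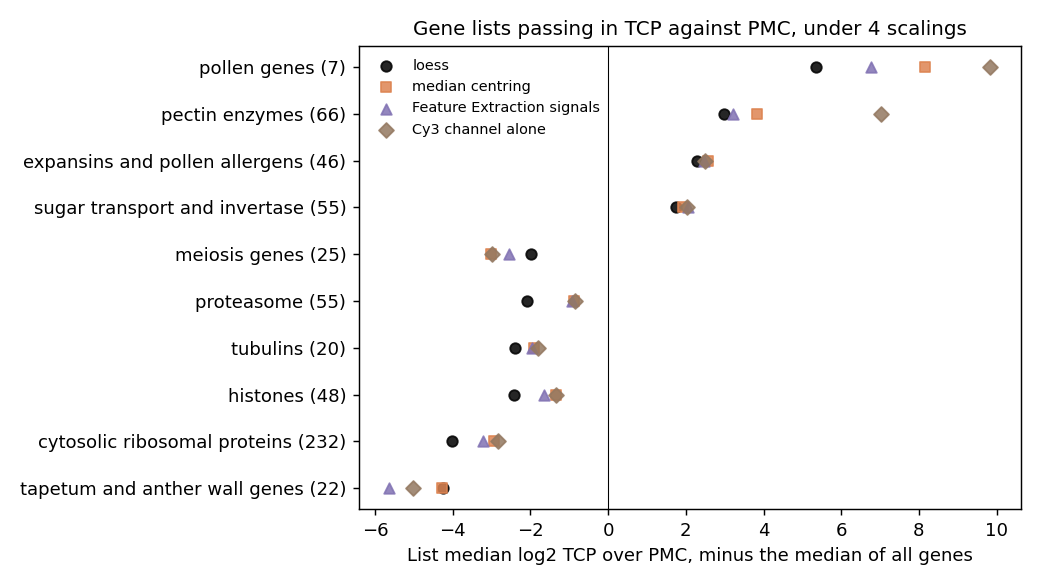
Points give the list median of the log2 difference of TCP over PMC minus the median of all genes, for the 10 lists that passed, with the number of genes in brackets and 1 symbol per scaling. Every list kept its side of 0 under the 4 scalings, from 5.36 to 9.84 for pollen genes and from -2.83 to -4.01 for cytosolic ribosomal proteins.

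In TCP against PMC 10 of 31 lists passed, 4 higher and 6 lower, and 0 passed camera with an estimated correlation, where 1 had an unadjusted p under 0.05. Among lists that did not pass, peroxidases and lignin had 40 of 63 higher and 14 lower (camera adjusted p = 0.0867, passing under median centring with 0.0368, without TCP replicate 1 with 0.0149, without TCP replicate 2 with 0.0344 and without PMC replicate 1 with 0.0301). Of the others, transposable elements had 31 of 71 higher (0.153), lipid transfer proteins 13 of 24 higher (0.544) and WRKY factors 18 of 39 higher (0.435). F-box genes had 136 higher and 75 lower of 317 (0.680), heat shock proteins 42 and 34 of 119 (0.544) and cyclins 17 and 11 of 49 (0.994). Photosynthesis genes had 16 higher and 17 lower of 66 (0.379), kinesins and spindle genes 13 and 19 of 47 (0.147), DNA replication genes 9 and 8 of 28 (0.544) and auxin genes 23 and 26 of 70 (0.298). MADS-box genes had 11 higher and 13 lower of 31 (0.440), RNA silencing genes 3 and 6 of 14 (0.435), SKP1 genes 2 and 3 of 7 (0.440), and late embryogenesis abundant genes 7 and 6 of 19 (0.653). Recombination and cohesion genes had 11 higher and 6 lower of 31 (0.894). Actin genes had 22 higher and 20 lower of 62 (0.440), calcium signalling genes 38 and 29 of 107 (0.544), vesicle trafficking genes 37 and 32 of 106 (0.440), and pentatricopeptide repeat genes 3 and 3 of 10 (0.678), with a median below 0 and a mean above 0 in these 4 lists and in the late embryogenesis abundant list. MADS-box genes had a median above 0 and a mean below 0. DNA replication, recombination and heat shock lists had a median and a mean above 0 and a camera direction downwards. Under median centring the balance of calls turned for several of these lists, with F-box genes at 68 higher and 100 lower, heat shock proteins 28 and 39, cyclins 9 and 19, recombination 3 and 15, DNA replication 2 and 12, calcium signalling 30 and 48, vesicle trafficking 25 and 42, actin 20 and 27, and WRKY 9 and 11. The mitochondrial respiratory chain list had 8 of 30 higher and 1 lower (0.440), and it passed under median centring (adjusted p = 0.00128), with the scanner software's signals (adjusted p = 0.0141) and in the Cy3 channel alone (adjusted p = 0.00173).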

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

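The tests of causes in this part were chosen after the results were seen, except the test of pollen RNA in the seedling RNA.

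The seedling channel of the second PMC array had 84.77% of probes well above background, far from the other 3 seedling samples (80.11% to 80.77%). Such a distance appears by chance in about 1 of 20 groups, and it was found for 1 of 3 measures tried. The PMC channel of the same array was also the higher of the PMC channels (75.59% against 71.36%).

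Further results are differences between the ratios to seedling in TCP and in PMC, each passed by camera at the preset correlation and not with an estimated one. The list medians of TCP minus PMC were -1.50 for meiosis genes, -3.74 for tapetum and anther wall genes, 5.85 for pollen genes and -3.52 for cytosolic ribosomal proteins. They were -1.93 for histones, -1.90 for tubulins and -1.59 for proteasome genes, and 3.46 for pectin enzymes, 2.78 for expansins and pollen allergens and 2.23 for sugar transport and invertase genes. Of the probes called higher than seedling in TCP and lower in PMC, 1344 of 1346 also passed limma's test of TCP against PMC. In the opposite direction 1438 of 1438 did. Selection for opposite calls makes such a result nearly certain, so these counts add no evidence of their own.

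Design control spots, which no comparison used, also gave signal. Over the 4 arrays, 10.4% of 960 genome control spots were well above background in Cy3 and 9.58% in Cy5. Random control spots reached 10% in Cy3 and 3.33% in Cy5 (480 spots each), and artificial ones 3.12% and 1.25% (480 each). The sequences behind them are not given, so their source was not tested.

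The seedling signal was brighter on the TCP arrays where the pollen signal was bright: over 383 probes bright in TCP (Cy3 over 20000) and not above background in seedling on the PMC arrays, the Cy5 median was 821 on TCP arrays and 33.4 on PMC arrays. Cy3 light read in the Cy5 channel would be a near constant share of Cy3, whereas the 90th percentile of the share was 23.3 times the 10th and single probes repeated between the TCP arrays (r = 0.93 across probes), which argues against it as the whole cause. Different seedlings are argued against too, since 0.0519% of probes dim in TCP had Cy5 raised 2-fold against 16.8% of bright ones. Pollen RNA in the seedling RNA of those arrays was tested by whether probes reached 25% of the median share, and 91.9% did. Cy3 light in the Cy5 channel would pass this test too, so it cannot tell these sources apart. Unless probes differ widely in dye response, a fixed admixture would also give even shares, and the same spread counts against it. The PMC arrays showed the mirror image over 99 probes (median share 0.430%, against 0.698% for TCP). Admixture behind both would need PMC RNA in the seedling RNA of the PMC arrays as well. Ratios of the brightest genes may be understated on both sides, and no biological explanation was tested.

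Tapetum and anther wall genes were higher in PMC than in seedling. A dye effect of the probes is argued against, because the same probes in the same dye gave a TCP minus PMC median of -4.24 relative to all genes. RNA of tapetum cells in the PMC samples and expression in the pollen mother cells themselves cannot be told apart. On both PMC arrays 80% of the 25 genes with a probe were well above background, against 67.0% of all genes (exact one-sided binomial p = 0.118, genes not being independent), with TIP2 (Os01g0293100) at 8.03 over seedling and PKS1 (Os10g0484800) at least 227-fold higher. None of the 25 genes is in another list, how many of them pollen mother cells express is not known from the files, and the labels state no sort that would remove tapetum cells.

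Ribosomal protein genes were lower in TCP than in PMC. The list median relative to all genes lay between -2.83 and -3.22 under the other scalings, which argues against the loess scaling as the whole cause. A constant shift of an array cancels in this relative value, so the test could not find one. Before the subtraction, the list median was -3.47 under median centring. It was -3.41 with the scanner software's signals and -2.57 in the Cy3 channel alone. A few transcripts taking most of the TCP signal is argued against as the whole cause, because random lists matched on intensity had medians no lower than -1.27, against -3.52 for the list. Genes of the random lists were drawn independently, so their range is too narrow for a list with an estimated correlation of 0.299. A stage difference, with fewer ribosomal transcripts in mature pollen, is consistent with these values as a hypothesis and was not tested on other data. Different amplification of the TCP and PMC RNA was not tested, since the labels name no such step.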

How the results depend on the processing

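Of the alternatives in this part, lists without accidental members and probes whose seedling signal differed by under 2-fold between TCP and PMC arrays were chosen after the results were seen; the rest were planned. Causes were not tested except where the construction of the alternative is named.

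Counts of changed probes stayed within 1.5 times the reported count under most alternatives. An adjusted p under 0.01 gave 12086 for TCP against PMC and 13816 for PMC against seedling, a stricter threshold by construction. Requiring both channels above background on all arrays, which tests fewer probes, gave 15901 for TCP and 11334 for PMC against seedling. Without each replicate in turn, counts ran from 13647 to 18287 for TCP against PMC, 20333 to 27255 for TCP against seedling and 16889 to 19109 for PMC against seedling. Such fits leave 1 array in a group, assumed to vary like the others. Aquantile moved no ratio, so it tests nothing. Same-direction overlaps went from 13189 to 11951 at 2-fold and 12556 under median centring.

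The replicate numbers are shared between TCP and PMC by label only (correlation of deviations 0.0077 across probes). With them as a block, 18409, 26179 and 20359 probes changed for TCP against PMC, TCP against seedling and PMC against seedling, and 10, 14 and 14 lists passed. DMC1A (Os12g0143800, adjusted p = 0.0552) and RAD51C (Os01g0578000, 0.0509) were not called in TCP against PMC with the block, and meiosis genes had 2 higher and 11 lower. Slide and scan as a block were not run, because all arrays share both.

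With the positive and significant flag, detection was 73.2% in TCP, 82.12% in PMC and 88.82% in seedling, in the same order.

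Gene lists depended most on whether camera's correlation was preset or estimated. Its size alone does not account for this, because camera with an estimated correlation takes its p from the 2 residual degrees of freedom. Hardly any list could pass in that way, so these values neither undo nor uphold the calls at the preset correlation. Pectin enzymes in TCP against PMC had an estimated correlation of -0.003, below the preset 0.01. Their camera adjusted p nevertheless went from 0.000183 to 0.592. With an estimated one, 0 lists passed camera in TCP against PMC, 0 in TCP against seedling and 0 in PMC against seedling, where 1, 1 and 3 had an unadjusted p under 0.05 (adjusted p from 0.355 to 0.993). Without each replicate in turn, 10 to 11, 13 to 15 and 14 to 16 lists passed. Median centring gave 11, 11 and 19. Restricted to probes with similar seedling signal, 6 lists passed in TCP against PMC, 0 higher and 6 lower. The 4 higher lists lost their calls by camera: pectin enzymes (median 0.39, adjusted p = 0.904), expansins (0.87, 0.904), sugar transport (1.59, 0.167) and pollen genes (7.37, 0.157). Pectin enzymes in TCP against seedling were at -0.63 relative to all genes, a reversal. That restriction filters on seedling signal, which itself followed the Cy3 signal (correlation of Cy5 and Cy3 differences between TCP and PMC arrays 0.48 across 36411 probes). Seedling signal was raised 2-fold on the TCP arrays for 16.8% of 3757 probes bright in TCP. For probes not well above background in TCP the share was 0.0519%. The restriction thus drops bright pollen genes more often than dim ones, and keeps most of the bright ones. Over the settings that can move a median, apart from the estimated correlation, medians of passing lists kept direction and call in 204 of 225 values, 20 kept only the direction and 1, the pectin enzymes above, reversed. Without accidental members, sugar transport lost its call in TCP against PMC (adjusted p = 0.0867).

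Aquantile, the deposited values (which repeat the scanner software's signals) and arrays outside a comparison were not counted for named genes. Of the other 1196 values, some from settings that change only adjusted p, 1156 kept direction and call, 26 only the direction, 3 gained a call and 11 reversed, the reversals all in TCP against PMC. Under median centring MSH4 (Os07g0486000) was -0.37, DMC1A (Os12g0143800) -1.65, MEL2 (Os12g0572800) -1.29, RAD51C (Os01g0578000) -0.98 and TDL1A (Os12g0472500) -0.42. In the Cy3 channel alone they were -0.02, -1.09, -1.95, -0.10 and -0.35. DMC1A was also -0.38 with the scanner software's signals. The cause was not tested.

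Signal over background limits ratios of dim genes, which are given as bounds or named as not well above background.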

Other observations

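Probes for miRNA genes were outside every gene list. Of the 340 spots carrying mature miRNA sequence, 17.6% and 17.1% were well above background in Cy3 on the TCP arrays and 16.8% and 22.1% on the PMC arrays. In Cy5 the same spots reached 14.1%, 14.7%, 13.5% and 19.7%. The second PMC array stood apart for the flanking sequences. On the 340 spots with 3' sequence it reached 37.1% in Cy3 and 39.1% in Cy5, against 18.8% to 23.2% over both channels of the other 3 arrays. On the 340 spots with 5' sequence it reached 34.1% and 34.4%, against 19.1% to 20%. Its seedling channel was the one with the most probes above background, and its PMC channel had 75.59% against 71.36% on the other PMC array.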
